A study of Homo sapiens with 6 samples.

How the data were processed

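Each of the 6 samples was measured on 1 Agilent array in 1 colour, with 3 si-control and 3 si-C1GALT1 samples taken 48 h after transfection. Per the file headers and the submitters' processing notes, the authors extracted spot intensities with Agilent Feature Extraction 10.5.1.1. The deposited scanner files give for each spot an intensity on a linear scale (the processed signal, which the software had background-subtracted and corrected for trends within the array), and it is not scaled between arrays. Per the file headers, they also give the median spot and local background intensity and flags for outliers, saturation and spots well above background. The authors' value table holds intensities as well. At least 99.9984% of its values per array were equal, with a tolerance of 0, to the background-subtracted signal of the same spot in the scanner files, so its scale is linear, with no scaling or centring. Its column medians lay between 120 and 149. Array medians of the processed signal lay between 127 and 164.

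Control spots (2075 of 62976) and spots flagged as outliers were left out. Spots of the same probe were averaged (300 of 58201 probes have 10 spots), and 100 probes with no unflagged spot on some array were dropped. The log2 processed signal minus the array's 75th percentile over non-control probes was used. A probe was tested if it was well above background on all 3 arrays of at least 1 group, which left 38839 probes. Probes were named by matching their unversioned RefSeq accession to a RefSeq gene table of GRCh38.p14. A symbol was found for 31104 probes, and the other 27097 kept the name in the files. The headers name another human build, so no coordinates are given. For a gene with several probes the brightest over all 6 arrays was taken, which gave 32319 genes, 17828 of them with a symbol from the table and 5269 with several probes. Of 401 called genes with several tested probes, 371 had the same sign in all of them, 235 had all of them called the same way and 0 had another probe called the opposite way by limma. A gene not well above background on any array of a group is given as a bound, the bright group's mean over the mean of, per array, the higher of the dim probe's signal and the lowest signal among probes well above background. This concerned 162 of the rises and 5 of the falls.

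Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, without a block, at a Benjamini-Hochberg adjusted p under 0.05, and positive log2 fold changes mean a higher signal after si-C1GALT1. The comparison, its alternatives, 41 gene lists and a rule for the genes to name were fixed before the data were examined. The rule took C1GALT1 and C1GALT1C1, the 10 protein-coding genes with the largest rise and the 10 with the largest fall among called genes of the same sign on all slides, and from each described list up to 4 called members with the smallest p, or 2 where none was called. FOSL1, TNS3, PTK2B and ROR1, which complete short lists of calls, were named after their values were seen. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 41 lists, and with an estimated correlation and with fry as alternatives. With camera 6 lists passed, all of them lower, while 0 passed with an estimated correlation (4 at an unadjusted p under 0.05) and 6 passed with fry. Camera compares a list with the other genes, whereas fry tests whether its genes move one way on balance. For C1GALT1 an exact permutation test was added.

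Arrays of a group correlated at 0.961 to 0.984 and arrays of different groups at 0.947 to 0.969, across genes. Replicate number, slide and scan coincide. Deviations from the group means of arrays with the same number correlated at 0.31 to 0.45, against -0.38 to -0.06 for other numbers in the other group. Deviations within a group sum to 0, so the negative values partly follow from the positive ones. The headers place arrays with the same number on a shared slide, so the numbers were taken to pair the samples. The fit without a block, fixed beforehand, was kept as the main fit, and the slide as a block is given as an alternative. The median coefficient of variation over replicate spots was 5.60 to 7.56% on 5 arrays and 25.3% on si-C1GALT1 replicate 2. Alternatives were quantile and median scaling, normexp background correction with an offset of 50 and quantile normalization, the authors' value table, no filter and a stricter filter on dim probes, the slide as a block, leaving out each array, an intensity trend with robust eBayes, array weights, the mean of a gene's probes, and other thresholds. Scaling to the spike-in probes, cyclic loess over the tested probes, the use of the median spot signal for normexp (the files hold no mean signal) and list medians within slides were chosen after the data were seen. The script was tested on simulated data with 32319 genes as in this comparison. Of 100 genes changed by 2 on the log2 scale 47% were recovered, and of 100 changed by 1 1% were, with 4% of the 50 calls false. With lists of random genes simulated likewise, the 1 list that was moved was called and 0 of the others were. The simulated genes varied independently and without slide effects, and far fewer genes were changed than were called in the data. With 50 calls against 1917 the adjusted p was harder to pass, so the shares recovered do not carry over. In the data the estimated correlation was 0.24 within the G2/M list and 0.69 within the histone list. The simulation therefore does not show how often camera calls lists of correlated genes in error.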

Results

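MIA PaCa-2 cells, a human pancreatic cancer cell line, were transfected for 48 h with a non-targeting control siRNA (si-control) or with siRNA against C1GALT1 (labelled si-C1GALT1-3, here si-C1GALT1). C1GALT1 encodes the core 1 synthase, which adds galactose to the first sugar of mucin-type O-glycans. Total RNA of 3 samples per group was labelled with the dye Alexa555 and measured on 1-colour Agilent arrays of 58201 non-control probes, 1 array per sample. Between 63.4 and 68.5% of these probes were well above background on the si-control arrays and between 70.9 and 72.3% on the si-C1GALT1 arrays. No spot was saturated, and the number of arrays limits the precision. Each of 3 slides carried 1 array of each group, and the replicate number is the slide number. The position on the slide differed between the groups in the same way on all 3 slides, so position and group cannot be told apart. The labels do not say that the samples came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The design asks which transcripts differ after knockdown of C1GALT1.

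The C1GALT1 transcript itself was lower on every si-C1GALT1 array than on every si-control array. Its log2 signal relative to the array's 75th percentile was -0.92, -0.90 and -0.87 on si-control replicates 1, 2 and 3, and -2.06, -2.09 and -2.26 on si-C1GALT1 replicates 1, 2 and 3. The group means were -0.90 ± 0.03 and -2.14 ± 0.11 (SD, n = 3 each), which leaves 42.4% of the control signal (95% interval of the limma fit 32.1 to 55.9%). The log2 fold change was -1.24 ± 0.17 (SE, limma adjusted p = 0.00994), and the 1 probe of C1GALT1 was well above background on all 6 arrays. The exact 2-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 arrays against 3 can give. C1GALT1 fell within each slide, by 1.13, 1.19 and 1.39 on slides 1, 2 and 3 on the log2 scale. By size of fall it ranked 633 among the called genes, and 842 of the tested genes had a lower log2 fold change. C1GALT1C1, the chaperone that C1GALT1 needs to fold, had a log2 fold change of 0.58 ± 0.18 and did not pass (limma adjusted p = 0.112). The call on the C1GALT1 level was lost without si-control replicate 3 (log2 fold change -1.22, limma adjusted p = 0.0620) and without si-C1GALT1 replicate 3 (-1.18, limma adjusted p = 0.0580), and also in the normexp alternative (-0.81, limma adjusted p = 0.0682) and in the authors' value table (-0.96, limma adjusted p = 0.101), within a range of adjusted p over the alternatives from 0.000214 to 0.101.

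**Figure D1:**
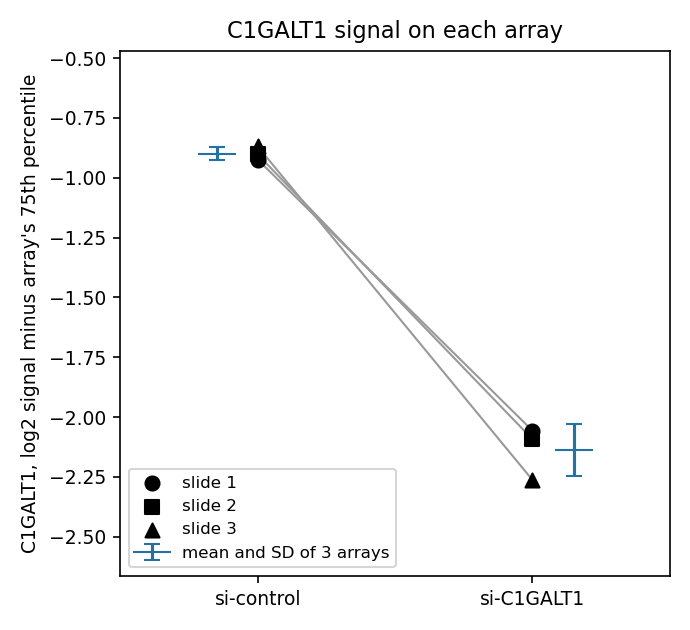
C1GALT1 signal on each of the 6 arrays, as log2 signal minus the array's 75th percentile, with a line joining both arrays of a slide and the mean and SD of the 3 arrays of a group beside the points. The si-control arrays lie between -0.92 and -0.87 and the si-C1GALT1 arrays between -2.26 and -2.06.

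Knockdown was accompanied by changes in both directions, with mitotic genes among the deepest falls and mostly weakly expressed genes among the steepest rises. Of 32319 genes tested with limma, 940 rose and 977 fell at an adjusted p under 0.05, and 768 of the rises and 846 of the falls were at least 2-fold. The balance of directions depended on scaling and on the filter on dim probes. By limma there were 862 higher and 600 lower after scaling to the spike-in probes, and 776 higher and 1000 lower after scaling to the median. After cyclic loess, which removes a trend with signal, there were 649 higher and 1006 lower. With no filter there were 413 higher and 580 lower, and with the stricter filter 826 higher and 1067 lower. The 1917 genes had the same sign on all 3 slides. Among protein-coding genes with a symbol, 561 rose and 828 fell. Large falls included PRC1, which organises the spindle midzone (log2 fold change -3.78 ± 0.21 SE), SPC25, a kinetochore subunit (-3.56 ± 0.22), and DEPDC1 (-3.29 ± 0.20). Log2 fold changes were -3.82 for PTX3, a secreted pentraxin, -3.54 for TAF9B, a subunit of the general transcription machinery, and -3.45 for the Mediator subunit MED21. NEMP1, a nuclear envelope protein, and ERCC6L, a helicase of anaphase DNA bridges, had the lowest estimates (-4.45 ± 0.94 and -3.96 ± 0.84), but without si-C1GALT1 replicate 2, whose replicate spots were the noisiest, these were -3.21 and -2.86 (limma adjusted p = 0.00822 for each). SGMS1, a sphingomyelin synthase, was not well above background on any si-C1GALT1 array and was at least 5.14-fold lower there, but in the normexp alternative its log2 fold change was -1.11, a smaller fall than that bound, and that of PTX3 was -2.59.

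The steepest rise was that of TK2, the mitochondrial thymidine kinase (log2 fold change 3.69 ± 0.39 SE), and P2RX6, an ATP-gated channel subunit, rose by 2.82 ± 0.31. Both were well above background on all 6 arrays. Another 5 of the 10 largest rises were not well above background on any si-control array and are given as bounds. DQX1 was at least 4.55-fold higher, the tryptophan dioxygenase TDO2 at least 4.01-fold, the endocytic recycling gene EHD3 at least 3.45-fold, LYSMD3 at least 2.17-fold and CFAP206, a cilia- and flagella-associated gene, at least 1.77-fold. DNAI7, an axonemal dynein gene (log2 fold change 3.46), HOGA1, a mitochondrial enzyme of hydroxyproline breakdown (3.21), and VPS35L, a subunit of an endosomal sorting complex (2.96), were well above background on 1 of the 3 si-control arrays. These folds depended on the processing. In the normexp alternative, which changes the background correction, the input signal and the scaling and adds an offset, the log2 fold changes were 1.20 for DQX1, 1.42 for TDO2, 0.97 for EHD3, 0.80 for LYSMD3 and 0.69 for CFAP206, below the bounds, and 1.71 for DNAI7, 1.54 for HOGA1 and 1.44 for VPS35L. The 10 largest rises and the 10 largest falls passed with limma adjusted p between 0.00184 and 0.0406. With the slide as a block the fit called 3356 genes, 1965 higher and 1391 lower, and 1896 genes were called the same way in both fits. Leaving out 1 array gave 748 genes without si-control replicate 2, 537 without si-control replicate 3, 788 without si-C1GALT1 replicate 1, 1248 without si-C1GALT1 replicate 2 and 517 without si-C1GALT1 replicate 3.

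**Figure D2:**
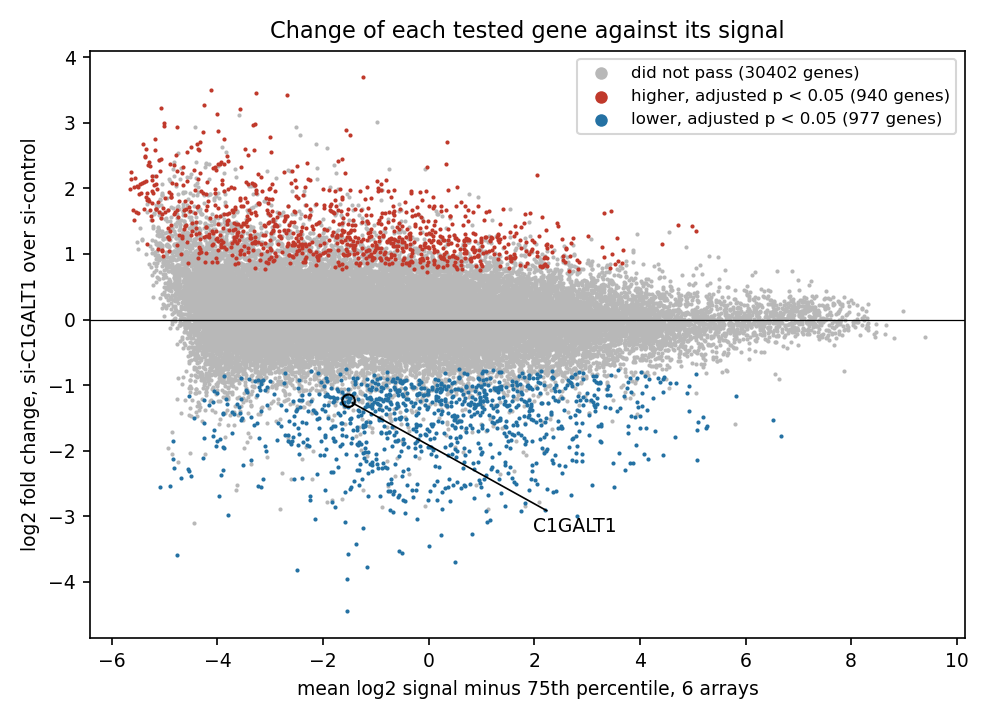
Log2 fold change (si-C1GALT1 over si-control) of each of the 32319 genes tested against its mean log2 signal relative to the 75th percentile over the 6 arrays, with the 940 genes that rose, the 977 that fell and C1GALT1 marked. The genes that rose lie further to the left (median mean signal -1.72) than those that fell (0.14).

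Genes of cell division fell as a group. Of 54 tested members of the G2/M and mitosis list, 50 fell, 4 did not pass and 0 rose, with 52 lower when adjusted over the list alone (0 higher at an unadjusted p under 0.05, and 0 with the slide as a block, by limma). The list's median log2 fold change was -2.16, a 4.48-fold lower signal, and the medians within slides 1, 2 and 3 were -2.23, -1.93 and -2.08. Its members with the smallest p included PRC1 and SPC25 (above), AURKB, the kinase of the chromosomal passenger complex (-2.91 ± 0.17 SE), and PBK, a mitotic kinase (-2.79 ± 0.17). Camera with the preset correlation gave the list an adjusted p = 4.82e-57, against an adjusted p = 0.230 with an estimated correlation, and fry gave an adjusted p = 0.000575 (0.0395 with the slide as a block). The number of members that fell was 41 without si-control replicate 3, its lowest, and 52 without si-C1GALT1 replicate 2.

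DNA replication genes and histone genes fell as well. In the G1/S and DNA replication list 31 of 46 tested members fell and 15 did not pass, with 41 lower when adjusted over the list alone. The median was -1.50 (-1.27, -1.74 and -1.66 within slides 1, 2 and 3). DTL, a substrate adaptor of a ubiquitin ligase active in S phase (-3.09 ± 0.21 SE), and the origin firing and licensing factors MCM10 (-3.04 ± 0.25), ORC1 (-2.58 ± 0.22) and CDC45 (-2.53 ± 0.20) had the smallest p. Of the 31 replication-dependent histone genes, 16 fell and 15 did not pass, with 28 lower when adjusted over the list alone and a median of -1.51 (-1.01, -1.38 and -2.08 within slides 1, 2 and 3). Examples were H3C2 (-2.48 ± 0.34), the linker histone gene H1-4 (-2.05 ± 0.24), H2AC6 (-1.80 ± 0.22; another probe of it gave -0.90 and did not pass) and H4C3 (-1.69 ± 0.21). The camera calls (adjusted p = 5.40e-33 and 2.35e-21) were lost with an estimated correlation, which gave an adjusted p = 0.277 with an estimated correlation for the replication list and 0.499 for the histones, and the fry calls (adjusted p = 0.00566 and 0.0464) were lost with the slide as a block (0.0899 and 0.155). Without si-control replicates 2 or 3, or si-C1GALT1 replicates 1 or 3, 17, 14, 17 and 15 replication genes and 8, 9, 8 and 5 histone genes fell, and without si-C1GALT1 replicate 2, 27 and 10 fell.

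Lists of MAPK output, YAP/TAZ targets and heat shock genes also leaned lower, with a minority of their members called. In the list of MAPK pathway output, 5 of 26 tested members fell, none of the other 21 passed, and 6 were lower when adjusted over the list alone. They were CCND1, cyclin D1 (log2 fold change -2.60 ± 0.21 SE), the secreted VGF (-2.19 ± 0.20), the EGFR ligand EREG (-1.62 ± 0.21), EMP1 (-1.51 ± 0.23) and FOSL1, an AP-1 subunit that was 4.01-fold lower. Of 21 tested YAP/TAZ targets, CCN1, a matricellular protein (-2.15 ± 0.23), the ecto-nucleotidase NT5E (-1.74 ± 0.19) and CRIM1 (-1.24 ± 0.17) fell, with 6 lower and 1 higher when adjusted over the list alone. Of 24 tested heat shock genes, the cytosolic chaperone HSP90AA1 (-1.53 ± 0.20) and its co-chaperone FKBP4 (-0.85 ± 0.18) fell, with 4 lower when adjusted over the list alone and 4 with the slide as a block. In the same order 21, 14 and 19 members had a log2 fold change below 0. List medians were -0.53, -0.41 and -0.36 and lay below 0 within each slide. Camera adjusted p were 3.37e-06 for MAPK output and 0.00229 for each of the others, against an adjusted p = 0.230, 0.484 and 0.499 with an estimated correlation in the same order. Fry gave adjusted p of 0.00566, 0.0225 and 0.0669, and with the slide as a block 0.0899, 0.135 and 0.135. Without si-control replicates 2 or 3, or si-C1GALT1 replicate 3, 3 MAPK output genes fell in each case, 2 YAP/TAZ targets fell without si-control replicate 3 or si-C1GALT1 replicate 3, and 1 heat shock gene fell without any array other than si-control replicate 1.

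**Figure D3:**
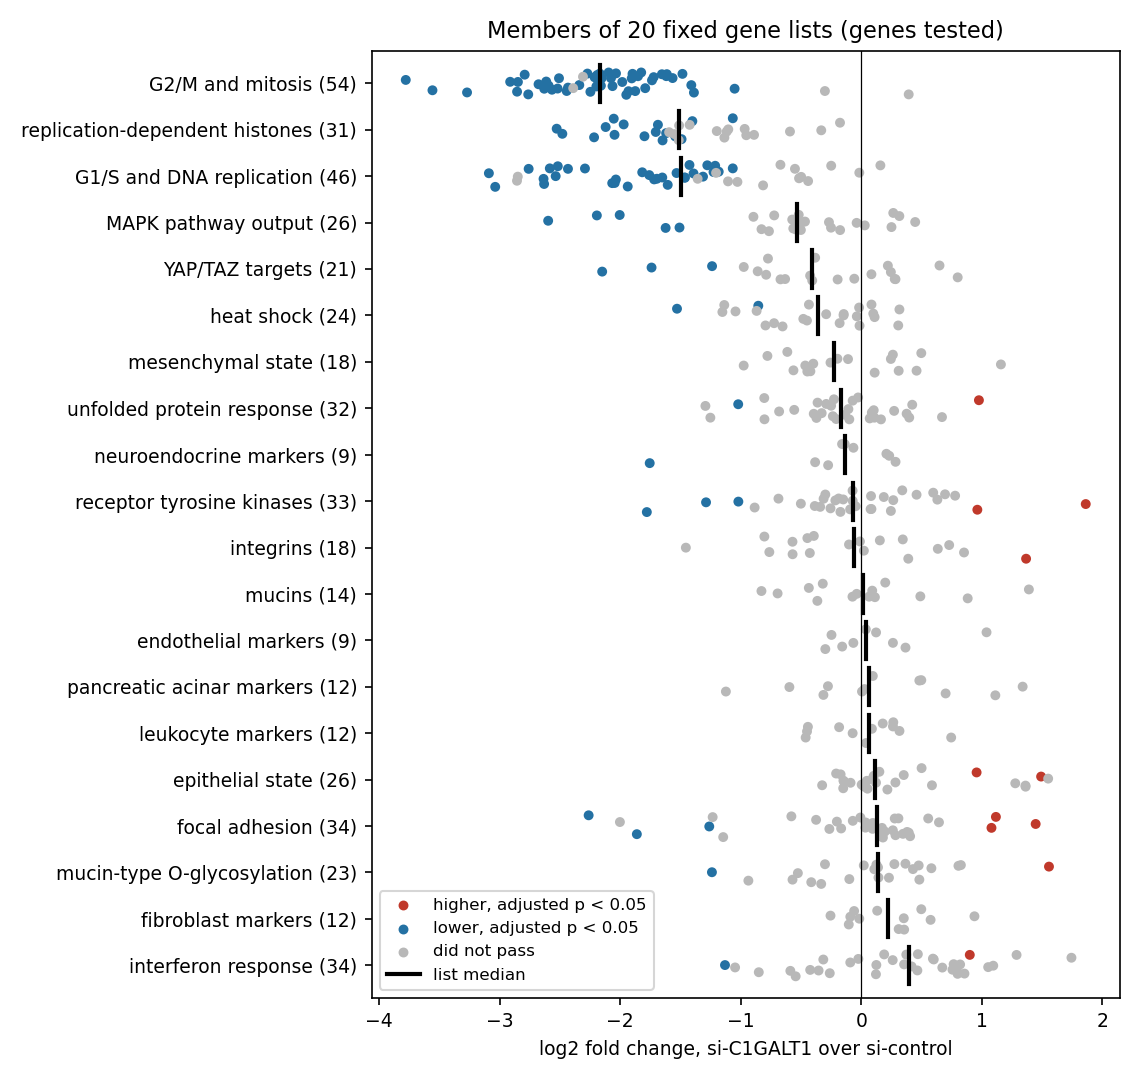
Log2 fold change (si-C1GALT1 over si-control, horizontal axis) of each tested member of 20 gene lists, coloured by whether it passed, with the list median as a black bar and the number of genes tested in brackets. Medians of the G2/M, replication-dependent histone and G1/S lists lie at -2.16, -1.51 and -1.50, below those of the other lists, which lie between -0.53 and 0.40.

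Few genes of the glycosylation pathway around C1GALT1 were called. Uncalled genes may have changed. The simulation recovered 1% of the genes changed by 1 on the log2 scale, but it made 50 calls against 1917 in the data. Its adjusted p was therefore harder to pass, and that share does not carry over to these genes. Of 23 tested members of the mucin-type O-glycosylation list, C1GALT1 fell, GALNT4, a transferase that starts O-glycans, rose (log2 fold change 1.56 ± 0.26 SE) and 21 did not pass, with 2 higher and 2 lower when adjusted over the list alone or with the slide as a block. By the brightest probe of each, none of 14 tested mucins passed limma's test over all genes, with 1 higher and 2 lower at an unadjusted p under 0.05, and 1 higher and 1 lower when adjusted over the list alone. CD164 had a log2 fold change of -0.83 ± 0.19 (limma adjusted p = 0.0510) and MUC1 of 1.39 ± 0.37 (limma adjusted p = 0.0810), and with the slide as a block these passed (limma adjusted p = 0.0442 and 0.0149). Another, less bright probe of CD164 gave -1.54 ± 0.20 and passed (limma adjusted p over probes = 0.00683). Fry's test for changes in either direction passed the O-glycosylation list, which holds C1GALT1 (adjusted p = 4.05e-05). It did not pass the mucins (adjusted p = 0.0505), but it passed the housekeeping list (adjusted p = 0.000146).

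Adhesion genes and growth factor receptors moved in both directions. Of 18 tested integrin subunits, ITGB6 rose (log2 fold change 1.37 ± 0.25 SE, well above background on 1 si-control array) and 17 did not pass, with 1 higher and 2 lower when adjusted over the list alone or with the slide as a block. Among 34 focal adhesion genes 3 fell, namely PARVA, an actin-binding partner of integrin-linked kinase (-2.26 ± 0.21), the adaptor CRKL (-1.86 ± 0.20) and paxillin, PXN (-1.26 ± 0.19), and 3 rose, namely GIT2 (1.12 ± 0.18; another probe of it gave -0.70 and did not pass), TNS3 (1.08 ± 0.18) and the kinase PTK2B (1.45 ± 0.32). PTK2B was well above background on 2 si-control arrays. Adjusted over the list alone, 3 focal adhesion genes were higher and 6 lower, and 3 and 5 with the slide as a block. Of 33 receptor tyrosine kinases, RYK (-1.78 ± 0.23), TYRO3 (-1.29 ± 0.18) and EGFR (-1.02 ± 0.18) fell, while MET (1.86 ± 0.29) and ROR1 (0.96 ± 0.19; another probe of it gave -0.73 and did not pass) rose, with 2 higher and 4 lower when adjusted over the list alone.

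Few epithelial genes and no mesenchymal genes passed in the main fit. Of 26 tested genes of the epithelial state, the transcription factor ELF3 (log2 fold change 1.49 ± 0.30 SE) and keratin 19, KRT19 (0.96 ± 0.20), rose and 24 did not pass, with the same numbers when adjusted over the list alone. The call of ELF3 was lost in 8 of the 18 alternatives and that of KRT19 in 9. Over all genes, 561 of the 14937 tested protein-coding genes rose. Of 18 genes of the mesenchymal state, 0 passed over all genes or over the list alone by limma, and 1 was higher and 4 lower at an unadjusted p under 0.05. Vimentin, VIM, had a log2 fold change of -0.78 ± 0.21 (limma adjusted p = 0.0772) and the transcription factor ZEB1 of -0.98 ± 0.28 (limma adjusted p = 0.0919), and with the slide as a block both passed (limma adjusted p = 0.0436 and 0.0252), as did 1 other member, which was higher. None of these 7 lists of glycosylation, mucins, adhesion, receptors and cell state passed camera (adjusted p between 0.226 and 0.872). The focal adhesion median (0.13) and mean (-0.09) differed in sign, as did the mucin median (0.01) and camera's direction.

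Stress lists and markers of other cell types had few called genes. Of 34 interferon response genes OAS3, a sensor of double-stranded RNA, fell (log2 fold change -1.13 ± 0.18 SE) and the ubiquitin ligase DTX3L rose (0.90 ± 0.20), with 6 higher and 2 lower when adjusted over the list alone, 5 and 2 with the slide as a block and 11 and 3 at an unadjusted p under 0.05. The interferon list's median was 0.40, the highest of the 41 lists, and camera passed it as higher in 2 of the 18 alternatives. Of 32 unfolded protein response genes the lectin chaperone CANX fell (-1.02 ± 0.18) and EDEM1, of the degradation pathway, rose (0.98 ± 0.18), with 1 each way when adjusted over the list alone and 1 higher and 3 lower with the slide as a block. Among 9 neuroendocrine markers synaptophysin, SYP, fell (-1.75 ± 0.17), also when adjusted over the list alone. No marker of acinar cells (12 tested), fibroblasts (12), leukocytes (12) or endothelial cells (9) passed limma's test over all genes or over its list alone. With the slide as a block 1 acinar marker passed as higher, and no fibroblast, leukocyte or endothelial marker passed. At an unadjusted p under 0.05, 2 acinar markers were higher and 1 lower, 0 fibroblast markers passed, and 1 leukocyte and 1 endothelial marker were higher. The 2 with the smallest p in each were CEL (-0.60 ± 0.19; another probe of it gave 0.16) and PTF1A (0.70 ± 0.27) for acinar cells, SFRP4 (0.94 ± 0.45) and COL1A2 (0.50 ± 0.34) for fibroblasts, GZMB (0.75 ± 0.29) and CD4 (-0.46 ± 0.21) for leukocytes, and PECAM1 (not well above background on any si-control array, so no fold change is given) and FLT1 (-0.30 ± 0.21) for endothelial cells. Camera adjusted p of these 7 lists lay between 0.186 and 0.998.

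The other 21 lists covered N-glycosylation, extracellular matrix, galectins, Golgi and vesicle traffic, lysosome and autophagy, immediate early genes, p53, NF-kB, TGF-beta, WNT, NOTCH, NRF2 and ATF4 targets, apoptosis, hypoxia and glycolysis, oxidative phosphorylation, cholesterol and fatty acid synthesis, small RNA machinery, ribosomal proteins and housekeeping genes. Of their 604 distinct tested genes, 16 rose and 26 fell. None of these lists passed camera (adjusted p between 0.0738 and 0.998), with list medians between -0.26 and 0.32, and by fry 1 did, the apoptosis list (adjusted p = 0.0105, and 0.123 with the slide as a block). In some of the 18 alternatives lists passed camera as higher, the lysosome and autophagy list in 9 and the ATF4 list in 7. In N-glycosylation and in cholesterol synthesis, as among leukocyte and endothelial markers, the median was above 0 while camera leaned lower. For galectins the median and camera leaned lower with a mean above 0, and for fatty acid synthesis the median lay below 0 with a mean above it.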

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

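The comparison of detected probes was made after the data were seen, and the tests of the dim genes were set before their own results were seen, that with cyclic loess after the others. More probes were well above background on the si-C1GALT1 arrays (41563 on average, between 41236 and 42107) than on the si-control arrays (37952 on average, between 36899 and 39863), with every si-C1GALT1 array above every si-control array. The median signal of the negative control spots was lower on the si-C1GALT1 arrays (5.26 to 5.72) than on the si-control arrays (7.05 to 9.88).

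The genes that rose were mostly dim, as 61.4% of them lay under the median signal of all tested genes, against 30.6% of the genes that fell. A general rise of dim probes on the si-C1GALT1 arrays was tested on the 8080 dimmest genes, whose median log2 fold change was 0.21, against 0.07, 0.01 and -0.04 in the next bins of equal size up to the brightest. There were 349 rises and 78 falls in the dimmest bin and 104 and 313 in the brightest. A median under 0.3 was to count against this explanation, but that bound was wrong, since a small shift of all dim genes is enough to tip the calls. A dim gene could also enter the test through 1 group alone, and more probes were detected on the si-C1GALT1 arrays. The bins therefore cannot separate a general rise of dim probes from an effect of the filter. The median over all tested genes was 0.05 with the main filter, -0.02 with no filter and 0.02 with the stricter filter. With the trend against signal removed by cyclic loess, 174 genes rose and 135 fell in the dimmest bin, so that rises were 56.3% of its calls, against 40.7, 36.8 and 27.7% in the next bins up to the brightest (108 rises and 282 falls). This fits a smooth trend of the fold change with signal as an explanation of part of the excess of dim rises, and a gradient remained without it. The loess would also remove a real rise of dim genes, so the source of the trend stays open. Background subtraction by the scanner software was tested with the normexp alternative, under which 93.6% of the rises (880 of 940) were still higher at an unadjusted p under 0.05, with a smaller median log2 fold change of 0.91, and 55.4% (521) were called at an adjusted p under 0.05. A share over 80% at the unadjusted p was to count against this explanation, but that bound was wrong, since the genes had been chosen for rising on the same arrays. The background subtraction therefore stays open as a cause. An effect of the position on the slide stays open, since position follows the group on every slide, and so does a response of the cells to the siRNA.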

How the results depend on the processing

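Scaling to the spike-in probes and cyclic loess over the tested probes were chosen after the data were seen. The spike-in scaling shifted the median log2 fold change of all genes from 0.05 to 0.18, so changes are relative to that. The 1917 calls by limma became 1265 with the authors' value table, 993 with no filter on dim probes (more genes tested), 3356 with the slide (replicate block), 862 higher and 600 lower with spike-in scaling, 776 higher and 1000 lower with median scaling, 649 higher and 1006 lower with cyclic loess, and 10106 with array weights, which gave si-control replicate 3 a weight of 8.33. At an adjusted p under 0.01 there were 464 and at an unadjusted p under 0.05 6950. Leaving out 1 array gave 517 (without si-C1GALT1 replicate 3) to 1598 genes (without si-control replicate 1), with 748 without si-control replicate 2, 537 without si-control replicate 3, 788 without si-C1GALT1 replicate 1 and 1248 without si-C1GALT1 replicate 2, where fewer samples enter the fit. The C1GALT1 level stayed lower in all 18 alternatives, between -1.34 and -0.81. Its call was lost with normexp (-0.81, limma adjusted p = 0.0682) and the authors' table (-0.96, limma adjusted p = 0.101), and the values without 1 array ran from -1.28 to -1.18, not called without si-control replicate 3 (limma adjusted p = 0.0620) or si-C1GALT1 replicate 3 (limma adjusted p = 0.0580). Of the 41 lists, camera called 11 with no filter on dim probes, 10 with cyclic loess, 6 to 10 when 1 array was left out (10 without si-control replicate 1) and 0 with an estimated correlation, and the 6 lists called kept their direction and their camera call with the preset correlation in every other setting run. Lists that gained a camera call were all higher, namely lysosome and autophagy in 9 of the 18 alternatives, ATF4 in 7, oxidative phosphorylation in 4 (quantile, normexp, no filter and cyclic loess), interferon response in 2 (no filter and without si-control replicate 1), ribosomal proteins in 2 (without si-control replicate 1 and cyclic loess) and the epithelial state in 1 (no filter). Of the 99 other named genes none changed sign past the threshold in any setting that tested it, and the stricter filter tested 80 of them. Some of the 99 had no call in the main fit. Among those called, the calls of 47 ended without si-control replicate 3 and of 45 without si-C1GALT1 replicate 3. Apart from the results printed with it, the block changed no call of a named gene or camera list. Where not stated, the cause was not tested. Some dim genes were not well above background on some arrays, so their folds are uncertain. Normexp gave smaller folds for those among the largest changes.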

Other observations

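Genes in this paragraph and the next were named after their values were seen. In the apoptosis list 5 of 35 tested genes fell and 1 rose, with 9 lower and 3 higher when adjusted over the list alone. Falls included BIRC5, which also acts in mitosis (log2 fold change -2.59 ± 0.17 SE), the apoptosome subunit APAF1 (-1.55 ± 0.22), the death receptor FAS (-1.22 ± 0.17) and BID (-0.94 ± 0.18), and BCL2L11 rose (1.46 ± 0.21), while its other probes gave 0.92, which passed, and -0.67, which did not. Fry passed this list (adjusted p = 0.0105), but not with the slide as a block (0.123), and camera did not (0.149), with a list median of -0.07. Among 45 genes of Golgi and vesicle traffic, the cargo receptor TMED10 fell (-2.50 ± 0.21), as did the coat genes SEC23A (-1.37 ± 0.20) and ARCN1 (-1.04 ± 0.19) and the cargo receptor subunit MCFD2 (-1.09 ± 0.20), and GOLGA4 rose (0.91 ± 0.19), with 5 lower and 3 higher when adjusted over the list alone. The hyaluronan receptor CD44 fell (-1.39 ± 0.22; another probe of it gave -0.66 and did not pass), the only called gene of 15 in the list of galectins and O-glycan binding, also when adjusted over the list alone. Of 25 NF-kB and inflammatory genes CXCL8 (-1.79 ± 0.29) and NFKB2 (-0.79 ± 0.17) fell and TRAF1 (1.21 ± 0.27) and CSF1 (1.09 ± 0.23; its other probes gave 1.56, which passed, and 0.15, which did not) rose, and of 24 TGF-beta response genes TGFB1 (-1.31 ± 0.22) and TGFBR2 (-1.24 ± 0.24) fell and SMAD6 (1.68 ± 0.37) and SMAD2 (1.32 ± 0.29) rose. TRAF1 was well above background on 1 si-control array and SMAD2 on 2. Adjusted over the list alone, the NF-kB counts were 2 each way and the TGF-beta counts were 2 lower and 4 higher, and camera passed none of these lists.

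Protein-coding genes were also grouped by the start of their symbol, a grouping chosen after the data were seen, which gave 172 families of at least 10 genes. Of 33 cilia- and flagella-associated (CFAP) genes CFAP206, CFAP96 (log2 fold change 1.93 ± 0.25 SE), CFAP300 (1.64 ± 0.35) and CFAP144 (1.29 ± 0.19) rose and CFAP20 (-1.30 ± 0.17) fell, with a family median of 0.46. Those that rose were dim, with mean signals from -5.18 to -3.11 against a median of -0.94 for all tested genes. CFAP96 and CFAP300 were each well above background on 2 si-control arrays. In the normexp alternative the 4 rises were 0.69, 1.00, 0.96 and 0.54 in the same order. Whether the family rose apart from the trend of dim genes was not tested. Of 15 intraflagellar transport (IFT) genes IFT70B (1.20 ± 0.18) and IFT27 (0.82 ± 0.19; another probe of it gave 0.16) rose, with a median of 0.57. Camera passed both families (adjusted p = 0.00664 each), against an adjusted p = 0.966 with an estimated correlation for each. The DRC family, of the dynein regulatory complex of cilia, did not pass camera (adjusted p = 0.112, with 3 of 10 genes higher and a median of 0.70). Fry gave an adjusted p of 0.0472 for DRC and 0.0389 for CFAP, and IFT did not pass it (0.0523). No list of cilium genes was fixed beforehand, so cilium genes as a set were not tested. In all 6 of the 172 families passed camera. The minichromosome maintenance (MCM), kinesin (KIF), nucleoporin (NUP) and RAD families did so as lower, with 7 of 10, 9 of 34, 3 of 22 and 5 of 18 genes lower and 0, 2, 0 and 0 higher, and medians of -1.73, -0.45, -0.41 and -0.12. With an estimated correlation the adjusted p was 0.933 for MCM and 0.966 for the others.

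The tests of S phase and of the siRNA below were chosen after the results were seen. The fall of the mitotic list was set against 3 technical explanations. Noise of the si-C1GALT1 replicate 2 array is argued against by a list median of -2.13 without that array, and scaling between arrays by medians of at most -1.96 under the 4 other scalings. A local spatial artefact is argued against by the 487 tested probes printed next to the list's probes, whose median log2 fold change was 0.0536. Loss of C1GALT1, another effect of the siRNA and an effect of the array's position on the slide cannot be told apart as causes of the fall. Position follows the group on every slide, and the labels give 1 siRNA treatment against C1GALT1 (si-C1GALT1-3), with no rescue. The labels give it as a single treatment while the series design speaks of siRNAs, so whether it is a pool is not known. A slower cell cycle after loss of C1GALT1 may be a biological explanation, and it stays an untested hypothesis, which counts of dividing cells with another siRNA and with C1GALT1 put back would decide.

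The fall of the replication-dependent histones, whose transcripts lack a poly(A) tail, was set against lower recovery of such RNA. The 256 small nucleolar and small nuclear RNAs tested, which lack the tail too, had a median log2 fold change of -0.13 (0 fell and 6 rose by limma). This argues against a loss of RNA without the tail that reaches these small RNAs. Whether their recovery follows that of histone transcripts was not tested. Whether there were fewer cells in S phase stays open. The median of -1.50 for the G1/S and DNA replication list was known when that test was set, so it does not test this hypothesis. A measurement of DNA content or of DNA synthesis per cell would decide it. The cell division, replication and histone lists together hold 97 of the 977 genes that fell, or 9.93%.

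The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Every split but the real one mixes arrays of both groups. A difference between the groups then widens the spread within each part, which lowers the limma and fry counts. Part of that difference also remains in the list medians. The other splits therefore do not show what arrays without a difference would give. By limma the real split called 1917 genes and 1 of the 10 splits gave as many, the real one, while the highest of the others was 0 genes (206 to 3384 genes at an unadjusted p under 0.05, against 6950). For lists by camera, 7 of the 10 splits gave as many as the real split's 6, and the highest of the others was 20, for si-control replicates 1 and 3 with si-C1GALT1 replicate 1 against the rest. The 3 other splits that, like the real one, part the arrays of every slide gave 4, 5 and 6 lists, and the splits that keep a slide together gave 1 to 20, so differences between slides enter these counts. Fry gave 6 lists in the real split and 0 in the others. The G2/M list's median had a size of 2.16 in the real split and of at most 0.87 in the others, with -1.50 and a size of 0.79 for the replication list, sizes of 1.51 and 0.82 for the histones and 0.53 and 0.30 for MAPK output. For YAP/TAZ targets (0.41 and 0.35) and heat shock genes (0.36 and 0.25) the sizes lay closer together. As the other splits mix the groups, no conclusion is drawn from these sizes.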
